A study of Homo sapiens with 18 samples.

How the data were processed

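The study measured which RNAs lie close to DDX6, an RNA helicase of P-bodies, in i3Neurons, an established line of neurons made from induced pluripotent stem cells. The method was ARTR-seq, in which a reverse transcriptase fused to protein A/G is brought to an antibody in fixed cells and copies the RNA around it into biotinylated cDNA. Libraries came from neurons at day 14 that had carried a first shRNA (control or TDP-43) for 8 days and a second shRNA (control or DCPS, the scavenger decapping enzyme) for 6 days. The 18 libraries form 6 groups of 3: control, TDP-43 knockdown, and TDP-43 plus DCPS double knockdown, each with the anti-DDX6 antibody and as an input without it. No group among the samples received the DCPS shRNA alone, and 1 batch label covers all libraries.

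The deposited table holds counts of reads in 96695 peaks for all 18 libraries, with 1 peak list shared by all of them. For the samples the authors name cutadapt 5.0, Bowtie2 2.3.5.1, STAR without a version, MACS3 3.0.2 and Subread 2.0.1, and the human build GRCh38. How peaks of single libraries were merged, how duplicates or molecular identifiers were handled, and how reads matching several loci were counted are not given in the sources used here. Intervals and floors given below cover counting error only. Peaks were 31 to 5652 bases long with a median of 97. A peak was assigned to a gene when it touched exactly 1 RefSeq gene span and lay on the strand that most peaks of that span use, which placed 85861 peaks (88.8%) in 8652 genes. The annotation used here holds gene spans without exons or sequence, so exons, untranslated regions and GC content were not analysed here.

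Counts were tested in R 4.3.3 with edgeR 4.0.16. Peaks were kept by filterByExpr with its minimum count of 10 and the 6 groups, which left 73182 peaks; 7968 genes were tested on counts summed over their peaks. TMM factors scaled the libraries, and 1 quasi-likelihood fit with a mean for each of the 6 groups (12 residual degrees of freedom) gave 12 contrasts. Of these, 3 compare DDX6 with input libraries, 3 compare the DDX6 libraries of the conditions, 3 compare their input libraries, and 3 test whether the DDX6-to-input ratio differs between conditions. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and a peak or gene was called at an adjusted p under 0.05. The biological coefficient of variation was 7.54% for peaks and 5.97% for genes. Log2 fold changes are given ± their standard error from this fit, and CPM (counts scaled to library sizes after TMM) as mean ± SD over 3 libraries.

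Peaks named in the text follow a fixed rule. Named are up to 10 per contrast and direction with the largest change among called peaks at or above the median abundance. In contrasts of 2 groups the groups must also not overlap, so that all 3 libraries of a group lie on 1 side of all 3 of the other. This demand was not made in the 3 contrasts of the DDX6-to-input ratio between conditions. Any other named peak is said to be chosen later. For 3 libraries against 3, chance separates the groups in 10% of peaks. Where a group had no count, a fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio has a 95% counting interval. Gene groups were 27 fixed lists, 23 of them with at least 3 tested members. Lists can share members, so their calls are not independent. SESN2 is both a p53 and an integrated stress response target, and UNC13A is on the synaptic vesicle and the cryptic splicing lists. The lists of mitochondrially encoded transcripts (0 tested), innate immune response (2), pluripotent cells (1) and glia (2) were too small to test. Lists were tested with camera of limma 3.58.1 on the gene sums with a preset correlation of 0.01, adjusted over the lists within a contrast. Of 94 list calls, 21 held with a correlation estimated from the data. For 44 of 276 list results the median, the mean and the test differed in sign, and 0 of these were called.

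The contrasts, tests, lists, naming rule and first set of alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0 size factors, total counts, the DESeq2 Wald test, no filter, the replicate number as a block, only the libraries of a contrast, gene sums, an estimated correlation and leaving out each library. Added later were edgeR's newer quasi-likelihood method, a fit with TDP-43 knockdown input replicate 3 as the only library of its group, and peak length and distance to the 3' end of the gene as features. The pipeline was tested on simulated data. With 200 peaks at or above the median abundance changed in each library type of counts simulated at the same depths, 47.8% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes were recovered between TDP-43 knockdown and control DDX6 libraries, 8.96%, 29.9% and 66.7% between their input libraries, and 2.26%, 17.3% and 66.7% for the difference of their DDX6-to-input ratios. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.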

Results

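The data are 18 ARTR-seq libraries of day 14 i3Neurons, 3 for each of 6 groups: control, TDP-43 knockdown and TDP-43 plus DCPS double knockdown, each with the anti-DDX6 antibody (DDX6 libraries) or without it (input libraries). TDP-43, encoded by TARDBP, is an RNA-binding protein lost from the nucleus of neurons in amyotrophic lateral sclerosis. DCPS hydrolyses the cap left after decay of an mRNA from its 3' end. The DDX6 libraries held 5879410 to 7265981 counts in peaks. The input libraries held 1266797 to 1572008 counts, except TDP-43 knockdown input replicates 1 (174698 counts) and 2 (288129 counts). A count of 3 equals 17.2 CPM in the first and 10.4 CPM in the second of these shallow libraries, against 0.413 to 2.37 CPM elsewhere. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

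TARDBP RNA fell in both knockdown conditions. In DDX6 libraries its 8 peaks summed to 87.1 ± 1.01 CPM (SD, n = 3) in control, 3.34 ± 0.597 after TDP-43 knockdown (3.84% of control) and 5.26 ± 1.01 in the double knockdown (6.05%). The changes against control were -4.69 ± 0.14 (adjusted p = 1.59e-18) and -4.03 ± 0.13 (3.03e-18) on the log2 scale. TARDBP was 1.58-fold higher in the double than in the TDP-43 knockdown (0.66 ± 0.25, adjusted p = 0.0336). In input libraries TARDBP fell by 2.55 ± 0.19 (3.52e-10) and by 2.57 ± 0.15 (1.44e-12). There TARDBP did not pass the test between the double and the TDP-43 knockdown (-0.02 ± 0.27, adjusted p = 0.973). DCPS had a single peak with 28 counts in control DDX6 libraries, 25 after TDP-43 knockdown and 4 in the double knockdown, or 1.67 ± 0.33, 1.34 ± 0.435 and 0.205 ± 0.0841 CPM. The DCPS peak did not pass the filter on low counts and was not tested. DDX6 mRNA itself was higher in DDX6 than in input libraries of control neurons (1.42 ± 0.09, adjusted p = 9.3e-13). It rose after TDP-43 knockdown from 1552 ± 62.7 to 2356 ± 57.1 CPM (0.60 ± 0.09, adjusted p = 2.96e-06). In the double knockdown DDX6 mRNA stood at 1751 ± 19.4 CPM, a log2 change of -0.43 ± 0.09 against TDP-43 knockdown (adjusted p = 0.000301). In input libraries DDX6 mRNA also rose after TDP-43 knockdown (0.37 ± 0.10, adjusted p = 0.00785). Its DDX6-to-input ratio changed by 0.23 ± 0.13, which did not pass the test (adjusted p = 0.233).

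**Figure D1:**
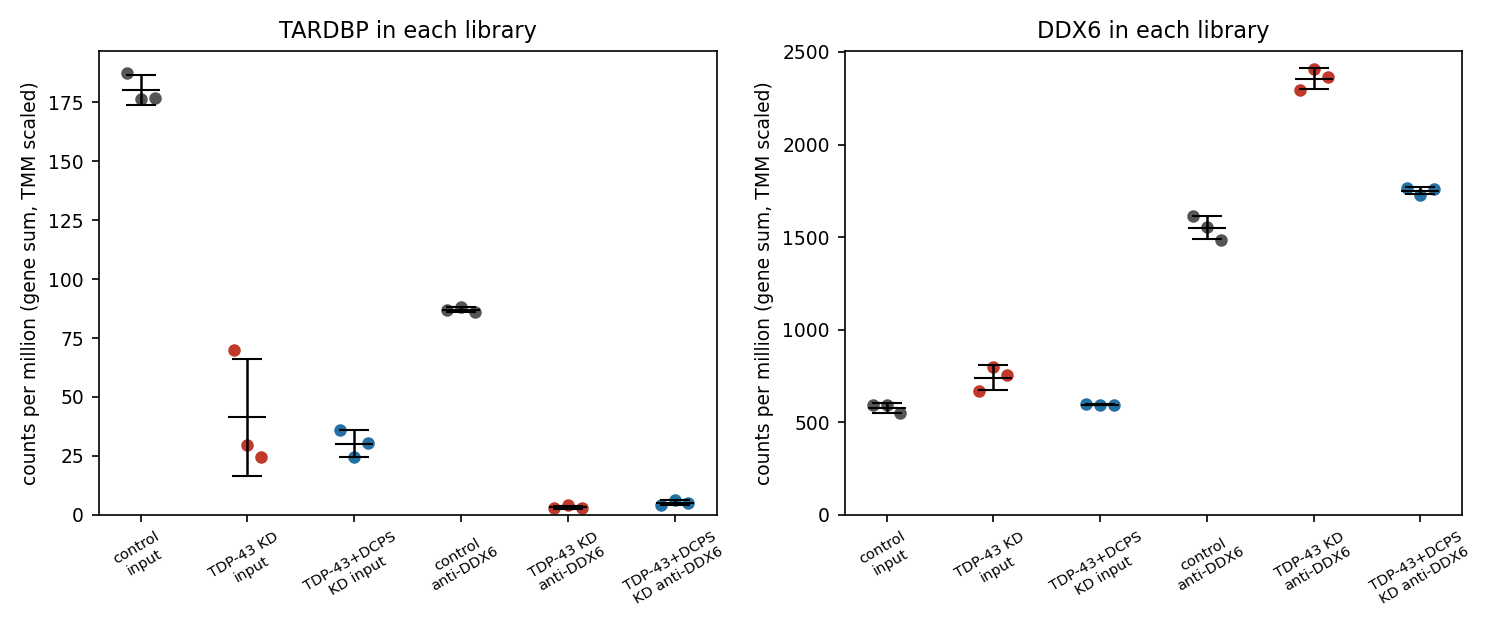
CPM of TARDBP (left) and DDX6 (right), summed over peaks, in each of the 18 libraries; points are libraries, black bars the mean ± SD of 3. TARDBP in DDX6 libraries drops from 87.1 CPM in control to 3.34 and 5.26, and DDX6 rises from 1552 to 2356 CPM before standing at 1751 in the double knockdown.

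The comparison of DDX6 with input libraries in control neurons asks which RNAs lie near DDX6. Some transcripts of the decay machinery itself were among those enriched, such as TOB1 (2.63 ± 0.10), which recruits deadenylases to mRNA, and CNOT6L (2.40 ± 0.09), a deadenylase. TNRC6B (2.03 ± 0.15), a partner of Argonaute in microRNA silencing, and AGO2 (1.77 ± 0.09) were enriched too. The most depleted named peak lay in TUBA1A, an alpha-tubulin, at 1220 CPM in input and 95.7 in DDX6 libraries (-3.67 ± 0.22, adjusted p = 2.76e-26). Peaks in CALM2 (-3.50 ± 0.25), a calmodulin gene, and HSP90B1 (-2.99 ± 0.14), an endoplasmic reticulum chaperone, were also depleted. Among the most enriched peaks, those of ZNF385D, NCOA3, RLF and PTCHD4 had 1 to 3 input counts, with ratios of 28.9 (5.12 to 1150), 27.2 (4.80 to 1082), 24.2 (6.63 to 201) and 21.5 (7.29 to 105). Of 73182 peaks, 32124 were called, 16626 higher and 15498 lower in DDX6 libraries. Of the called peaks 30899 showed no overlap between the groups.

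Among fixed lists, P-body proteins and decapping factors had 12 of 25 members higher and 5 lower (13 and 5 adjusted over the list alone; camera adjusted p = 0.00406, and adjusted p = 0.0281 with an estimated correlation). TNRC6A was at 1.73 ± 0.12 and DCP1A at 1.58 ± 0.23. CCR4-NOT and PAN deadenylases had 11 of 17 higher and 2 lower (the same numbers adjusted over the list alone; 0.00097, and adjusted p = 0.0323 with an estimated correlation). Of these BTG2 was at 1.99 ± 0.19 and CNOT9 at -1.60 ± 0.10. Exosome and cap scavenging factors had 2 of 12 higher and 3 lower and were not called (adjusted p = 0.969). Transcripts of ZNF-named zinc fingers, mostly transcription repressors, had 281 of 386 higher and 24 lower (289 and 24 adjusted over the list alone; 1.31e-18, and adjusted p = 0.0211 with an estimated correlation). Axonal cytoskeleton transcripts had 0 of 27 higher and 25 lower, the same numbers adjusted over the list alone (1.2e-08, and adjusted p = 0.0211 with an estimated correlation), such as DPYSL3 (-1.79 ± 0.12) and TUBB3 (-1.62 ± 0.14). Synaptic vesicle transcripts had 21 of 27 lower and 4 higher (0.0034, and adjusted p = 0.0378 with an estimated correlation; SYN2 -1.39 ± 0.14, CPLX2 -1.38 ± 0.08). Cytosolic heat shock transcripts had 7 of 10 lower and 1 higher (0.000957, and adjusted p = 0.0323 with an estimated correlation; HSPA8 -2.14 ± 0.12). Oxidative phosphorylation had 31 of 50 lower and 0 higher (0.000239) and ribosomal proteins 40 of 72 lower and 2 higher (0.00526). Both calls were lost, at adjusted p = 0.644 and adjusted p = 0.76 with an estimated correlation. The share of higher peaks rests on the scaling: 51.8% of called peaks were higher with TMM, 65.9% with DESeq2 size factors and 66.8% with total counts. The median of all peaks moved from 0.12 to 0.38 and 0.40. Under both other scalings, 0 of the 94 list calls of all contrasts had most of their called members on the other side.

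Peaks enriched in control DDX6 libraries were longer and nearer to gene ends than the others. Their median length was 198 bases, against 88 for depleted peaks and 108 for peaks not called. Of enriched peaks in a gene, 49.8% lay within 5000 bases of the 3' end of the gene span, against 25.5% of depleted peaks (odds ratio 2.90, 95% interval 2.76 to 3.05, Fisher's exact test, two-sided) and 31.3% of peaks not called. Of peaks in a gene, long non-coding RNA genes held 1.02% of enriched and 0.416% of depleted ones (odds ratio 2.48, 1.82 to 3.41, Fisher's exact p = 8.15e-10). They held 0.718% of those not called. These features were chosen after the data were seen, and peaks of a gene are not independent of each other. The peak list itself comes from these libraries, so peak length may follow signal in the deeper DDX6 libraries and restate enrichment.

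TDP-43 knockdown changed the DDX6 libraries most at STMN2, which encodes stathmin-2, an axonal microtubule regulator whose transcript is known to take up a cryptic exon when TDP-43 is lost. Of its 7 peaks, the second from the 5' end (chromosome 8, 79616846 to 79617190) rose from 1.45 ± 0.308 to 136 ± 5.08 CPM (6.52 ± 0.23, adjusted p = 3.8e-42). The first, at the gene start, rose by 0.65 ± 0.14 (0.000151). The other 5 peaks of STMN2 fell, as they did in input libraries, the lowest by 2.90 ± 0.17 in DDX6 libraries, where the gene sum fell by 1.70 ± 0.14. A DDIT3 peak, of a transcription factor of the stress response, rose by 2.60 ± 0.32 (adjusted p = 2.33e-10). Peaks in IFRD1 (2.41 ± 0.19), EPC1 (2.11 ± 0.15) and CCAR1 (1.91 ± 0.12) rose too. The largest falls among named peaks were in RPL14 (-5.16 ± 0.28; 22.5 to 0.61 CPM), TARDBP (-4.06 ± 0.23) and the neuronal RNA-binding protein gene ELAVL3 (-3.59 ± 0.18). They also took in the long non-coding SNHG14 (-3.16 ± 0.14) and KALRN (-2.95 ± 0.14), a synaptic exchange factor. RPL14 has processed pseudogenes, and how reads matching several loci were counted is not known. In all, 23843 peaks were called, 11027 higher and 12816 lower, of which 2181 and 3972 changed at least 2-fold. The majority turns with the scaling: 46.3% of called peaks were higher with TMM, 53.5% with DESeq2 size factors and 55.3% with total counts.

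**Figure D2:**
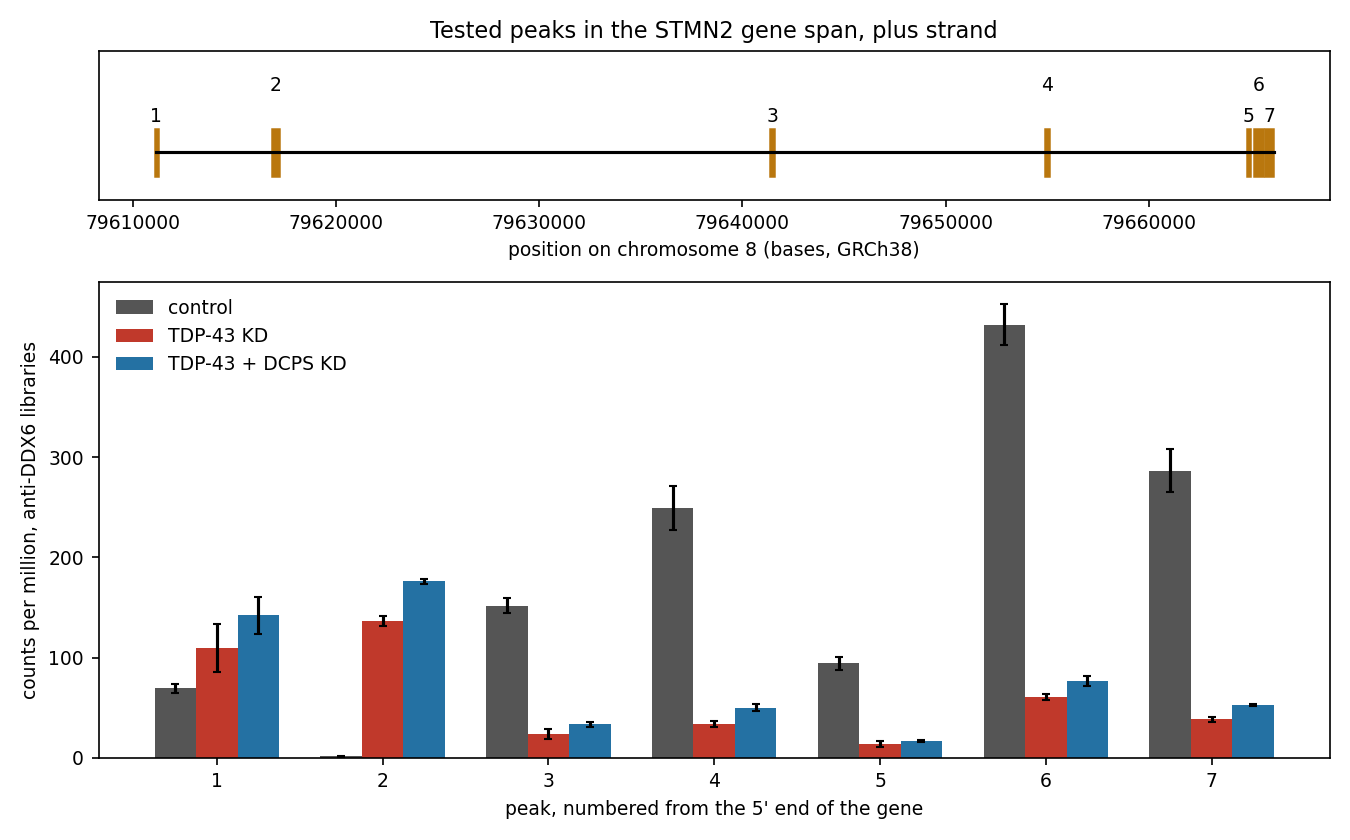
Top, the 7 tested STMN2 peaks on chromosome 8 (bases, GRCh38); bottom, their mean CPM in DDX6 libraries of control, TDP-43 knockdown and double knockdown neurons (bars, error bar SD, n = 3). Peak 2 goes from 1.45 CPM in control to 136 and 176, while peaks 3 to 7 lie below control in both knockdowns.

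Transcripts with known TDP-43-repressed cryptic splicing fell as a group after TDP-43 knockdown: 21 of 31 members were lower and 4 higher in DDX6 libraries, the same numbers adjusted over the list alone (adjusted p = 3.15e-09, and adjusted p = 0.0385 with an estimated correlation). The largest falls were in the insulin receptor gene INSR (-4.32 ± 0.20), ELAVL3 (-3.30 ± 0.13) and MADD (-2.88 ± 0.12). Integrated stress response targets had 13 of 18 higher and 1 lower, also adjusted over the list alone (0.00136, and adjusted p = 0.0979 with an estimated correlation). Among them ATF3 (2.21 ± 0.23), CEBPB (1.54 ± 0.22) and ATF4 (1.24 ± 0.08) rose. Replication-dependent histone transcripts, which end without a poly(A) tail, had 10 of 12 lower (0.000484, and adjusted p = 0.168 with an estimated correlation), such as H3C6 (-2.83 ± 0.18) and H2BC5 (-1.96 ± 0.15). Axonal cytoskeleton had 20 of 27 lower and 1 higher (0.00172, and adjusted p = 0.136 with an estimated correlation), MAP1A at -1.56 ± 0.16. Synaptic vesicle and active zone transcripts had 15 of 27 lower and 3 higher (0.00715, and adjusted p = 0.0979 with an estimated correlation). UNC13B (-2.72 ± 0.21), BSN (-1.41 ± 0.07) and UNC13A (-1.19 ± 0.12), all of presynaptic scaffolds or priming factors, fell. Postsynaptic transcripts had 16 of 26 lower and 3 higher (0.0212, and adjusted p = 0.168 with an estimated correlation; CAMK2B -1.46 ± 0.26, GRIN2B -1.34 ± 0.09). ALS and FTD genes had 14 of 26 lower and 5 higher (0.0212, and adjusted p = 0.136 with an estimated correlation; VCP -1.09 ± 0.20).

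Further calls of this comparison lay near the threshold. Stress granule protein transcripts had 12 of 20 lower and 0 higher (adjusted p = 0.0413, and adjusted p = 0.273 with an estimated correlation; TIAL1 -0.66 ± 0.07). Voltage-gated ion channels had 10 of 19 lower and 3 higher (0.048, and adjusted p = 0.61 with an estimated correlation; SCN2A -1.53 ± 0.19). Targets of p53 had 7 of 14 higher and 0 lower (0.048, and adjusted p = 0.136 with an estimated correlation; AEN 1.81 ± 0.27, SESN2 1.03 ± 0.12). Leaving out 1 of the 6 libraries ended these calls in 6, 5 and 4 cases, with highest adjusted p of 0.0619, 0.0738 and 0.0699. The ion channel call was also lost with a replicate block (0.0559), and that of p53 targets with DESeq2 size factors (0.0508) and with TDP-43 knockdown input replicate 3 alone (0.0553). P-body proteins and decapping factors had 9 of 25 members higher and 7 lower, against 2206 and 2172 of all 7968 genes, with no call as a list (adjusted p = 0.825). PATL1 was at 0.75 ± 0.07 and PNRC1 at -0.91 ± 0.07. CCR4-NOT and PAN deadenylases (7 higher and 3 lower of 17, adjusted p = 0.388), exosome and cap scavenging factors (2 and 2 of 12, 0.855) and ribosomal proteins (9 and 32 of 72, 0.118) were not called either. The same held for translation factors with 5' TOP motifs (4 and 7 of 15, 0.588), oxidative phosphorylation (6 and 3 of 50, 0.855) and ZNF-named zinc fingers (110 and 103 of 386, 0.855). It held for the unfolded protein response (5 and 2 of 14, 0.299), heat shock (5 and 0 of 10, 0.157), long non-coding RNAs (1 and 3 of 4, 0.152) and peripheral-like neuron markers (2 and 1 of 6, 0.855).

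Adding DCPS knockdown to TDP-43 knockdown raised a peak in SLC10A7, a member of the bile acid carrier family, from 3.37 to 40.5 CPM in DDX6 libraries, against 4.04 CPM in control (3.59 ± 0.16, adjusted p = 6.4e-33). SLC7A11, the cystine transporter subunit induced under stress, rose from 4.97 to 23.4 CPM (2.22 ± 0.17). Peaks in PDGFD (2.76 ± 0.26), H3C6 (2.70 ± 0.29) and the axon guidance genes SEMA3D (2.35 ± 0.18) and SEMA3E (2.10 ± 0.17) rose as well. Named peaks in the glutamate receptor genes GRIN2B, GRIN2A and GRIA3 fell by 2.38 ± 0.29, 2.24 ± 0.17 and 1.57 ± 0.14, while the postsynaptic list that holds these genes had 12 of 26 members higher and 5 lower and was not called (adjusted p = 0.306). CCAR1, raised after TDP-43 knockdown from 13.6 to 51.4 CPM, stood at 10.7 CPM in the double knockdown (-2.26 ± 0.13). The STMN2 peak 2 was higher again in the double knockdown, at 176 ± 2.57 CPM (0.37 ± 0.13, adjusted p = 0.0303). This rise was not particular to peak 2. Peaks 1, 3, 4 and 7 of STMN2 were also called higher, by 0.375 ± 0.137, 0.526 ± 0.164, 0.558 ± 0.175 and 0.453 ± 0.168. Peaks 5 and 6 (0.287 ± 0.164 and 0.337 ± 0.172) did not pass the test. In this comparison 17533 peaks were called, 9113 higher and 8420 lower, and leaving out 1 library left 11547 (without double knockdown replicate 1) to 12239. Of called peaks 52.0% were higher with TMM, 45.6% with DESeq2 size factors and 57.2% with total counts. With no group among the samples that received the DCPS shRNA alone, changes due to DCPS knockdown in neurons with TDP-43 were not measured.

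Histone transcripts rose after DCPS knockdown was added, in 11 of 12 members with 0 lower, the same numbers adjusted over the list alone (adjusted p = 8.28e-06, and adjusted p = 0.259 with an estimated correlation). H2AC17 was at 2.90 ± 0.37 and H2BC5 at 1.97 ± 0.15. Integrated stress response targets had 8 of 18 higher and 1 lower (8 and 2 adjusted over the list alone; 0.0384, and adjusted p = 0.27 with an estimated correlation). SLC7A11, TRIB3 (1.32 ± 0.17), DDIT4 (0.87 ± 0.12) and PPP1R15A (0.75 ± 0.08) rose and ATF4 fell (-0.33 ± 0.07). DDIT3 (-0.17 ± 0.24) and ATF3 (0.11 ± 0.16) did not pass the test. Neural progenitor and cycling markers had 2 of 4 higher and 1 lower (0.0384, and adjusted p = 0.259 with an estimated correlation). The intermediate filaments VIM (1.66 ± 0.08) and NES (0.72 ± 0.09) rose and the replication clamp PCNA fell (-0.91 ± 0.12). Axonal cytoskeleton had 16 of 27 higher and 0 lower (0.0385, and adjusted p = 0.436 with an estimated correlation; MAP1B 0.71 ± 0.11). Ribosomal proteins had 34 of 72 higher and 3 lower (0.0384, and adjusted p = 0.731 with an estimated correlation; RPLP2 1.21 ± 0.16). The unfolded protein response had 8 of 14 lower and 0 higher (0.0384, and adjusted p = 0.493 with an estimated correlation; HSP90B1 -1.23 ± 0.16), and heat shock 5 of 10 lower and 1 higher (0.0384, and adjusted p = 0.27 with an estimated correlation; BAG3 -1.75 ± 0.23). ZNF-named zinc fingers had 130 of 386 lower and 63 higher (0.0384, and adjusted p = 0.575 with an estimated correlation). Leaving out a single library ended the calls of the axonal, ribosomal and heat shock lists in 6 of 6 cases, with adjusted p up to 0.105. It ended those of the stress response, unfolded protein and zinc finger lists in 5 of 6, up to 0.0718. The unfolded protein call was also lost with a replicate block (0.0655), and the stress response call with TDP-43 knockdown input replicate 3 alone (0.0671). P-body proteins (6 higher and 7 lower of 25, adjusted p = 0.655), deadenylases (1 and 8 of 17, 0.0527) and cryptic splicing transcripts (11 and 2 of 31, 0.306) were not called.

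**Figure D3:**
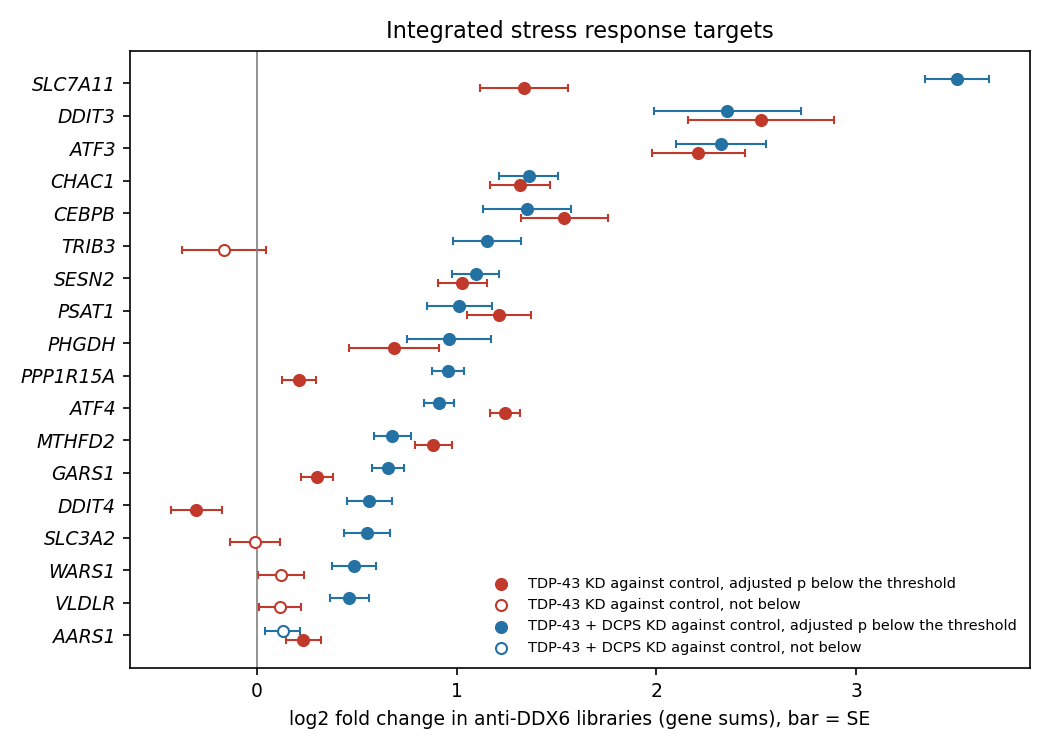
Log2 fold changes against control of the 18 tested integrated stress response targets in DDX6 libraries, after TDP-43 knockdown (red) and double knockdown (blue); points are gene sums with SE bars, and open points did not pass the test. SLC7A11 goes from 1.34 to 3.50, while DDIT3 (2.52 and 2.36) and ATF3 (2.21 and 2.32) stand close together.

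Set against control, the double knockdown kept the STMN2 peak as its largest rise in DDX6 libraries (6.89 ± 0.23, adjusted p = 1.58e-44). Next came SLC7A11 (3.66 ± 0.21), SLC10A7 (3.31 ± 0.16), the Notch ligand family member DLK1 (2.72 ± 0.20) and TXNIP (2.28 ± 0.13), an inhibitor of thioredoxin. Falls among named peaks were led by TARDBP (-3.72 ± 0.21), SNHG14 (-3.44 ± 0.14), GRIN2B (-3.37 ± 0.25) and ANO3 (-3.17 ± 0.22). Integrated stress response targets had 17 of 18 higher and 0 lower, also adjusted over the list alone (adjusted p = 7.11e-10, and adjusted p = 0.00426 with an estimated correlation). Cryptic splicing transcripts had 20 of 31 lower and 0 higher, also adjusted over the list alone (1.99e-08, and adjusted p = 0.0276 with an estimated correlation). INSR was at -4.21 ± 0.19 and ELAVL3 at -2.42 ± 0.12. ALS and FTD genes (10 of 26 lower and 4 higher, 0.0104; adjusted p = 0.111 with an estimated correlation) and synaptic vesicle transcripts (15 of 27 lower and 3 higher, 0.031; adjusted p = 0.148 with an estimated correlation) were called too. So were long non-coding RNAs (3 of 4 lower and 0 higher, 0.0301; adjusted p = 0.159 with an estimated correlation) and progenitor markers (2 of 4 higher and 0 lower, 0.0301; adjusted p = 0.111 with an estimated correlation; VIM 1.29 ± 0.08). Histones were not (3 higher and 2 lower of 12, adjusted p = 0.92). Of 19672 peaks called, 8929 were higher and 10743 lower, and leaving out 1 library left 12351 to 13085. Of called peaks 45.4% were higher with TMM, 47.8% with DESeq2 size factors and 60.1% with total counts. Synaptic vesicle and long non-coding calls were each lost without 1 library in 2 of 6 cases, with adjusted p up to 0.0666 and 0.0616.

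Peaks that changed after TDP-43 knockdown often changed the other way when DCPS knockdown was added. Of peaks called in both DDX6 comparisons, 8458 changed in opposite directions, such as CCAR1, and 658 in the same direction, such as the STMN2 peak 2 and SLC7A11. The fall-then-rise and rise-then-fall classes held 4189 and 4269 peaks, against 1596 and 1269 if the calls were independent. The TDP-43 knockdown libraries enter both comparisons with opposite sign, which alone gives a negative correlation. Across peaks Pearson's r was -0.503, within the range of 20 simulations of unchanged groups (-0.511 to -0.499). Leaving out 1 library gave -0.558 to -0.512, a setting that was not simulated. The covariance, -0.155, was larger in size than in these simulations (lowest -0.0257). A difference of the TDP-43 knockdown group from both others, of whatever origin, enlarges it. In input libraries 1937 peaks changed in opposite directions and 29 in the same direction, with r at -0.718 (simulated -0.729 to -0.719). Leaving out 1 library moved it from -0.904, without TDP-43 knockdown replicate 3, to -0.643. The covariance was -1.21 against a lowest simulated value of -0.524. The simulation gave each peak 1 dispersion for all groups. TDP-43 knockdown input replicates 1 and 2 differed more from replicate 3 (chi-square per degree of freedom 2.83 and 3.21) than replicates of other groups (at most 1.40). Their noise may thus be simulated too low, so the input covariance cannot tell this noise from a change. Peaks are not independent replicates, so no p is given.

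Input libraries sample RNA in the cells without the antibody. After TDP-43 knockdown the STMN2 peak 2 rose in them from 12.3 ± 2.21 to 88.1 ± 7.79 CPM (2.78 ± 0.29, adjusted p = 4.19e-12). Peaks 3 to 7 of STMN2 fell in them, by 2.51 ± 0.26 to 3.16 ± 0.22, much as in DDX6 libraries. Named rises included a peak in NFE2L2, an antioxidant transcription factor (2.82 ± 0.68), and named falls SEMA3D (ratio 30.3, 8.23 to 253) and ANP32B (-3.80 ± 0.52). A PTBP1 peak, of a splicing repressor, rose with a ratio of 10.6 (2.99 to 56.9), a call lost without TDP-43 knockdown input replicate 3 (adjusted p = 0.103). Integrated stress response targets had 9 of 18 higher and 1 lower (10 and 1 adjusted over the list alone; 5.49e-06, and adjusted p = 0.00968 with an estimated correlation), with DDIT3 at 3.78 ± 0.71. Cryptic splicing transcripts had 13 of 31 lower and 2 higher (0.000256, and adjusted p = 0.0372 with an estimated correlation), with ELAVL3 at -2.62 ± 0.15. Both calls were also made with replicate 3 as the only library of its group, a fit in which the spread comes from the other groups alone, as were those of p53 targets (8 of 14 higher, 0.0105, and adjusted p = 0.066 with an estimated correlation; adjusted p = 0.0529 without replicate 3). The same fit called long non-coding RNAs (2 of 4 lower, 0.00733, and adjusted p = 0.0895 with an estimated correlation). Ribosomal proteins (35 of 72 higher and 1 lower, 3.99e-15; adjusted p = 0.278 with an estimated correlation), 5' TOP translation factors (9 of 15 higher, 0.000132; 0.372) and oxidative phosphorylation (7 of 50 higher, 4 adjusted over the list alone, 0.000239; 0.372) lost their calls with replicate 3 alone, at adjusted p of 0.133, 0.276 and 0.974. So did postsynaptic transcripts (7 of 26 lower, 0.0408; 0.0899) and ion channels (5 of 19 lower, 0.0224; 0.372), at 0.453 and 0.938, and without 1 library in 2 of 6 cases each (up to 0.0984 and 0.102). The shallow replicates 1 and 2 differed from replicate 3 by more than counting error (chi-square per degree of freedom 2.83 and 3.21, against 1.03 to 1.40 within the other groups). They also differed from each other (1.54). Of 4076 called peaks, 602 were higher and 3474 lower. As gene sums, 936 of all 7968 genes were higher and 1160 lower, a share that the 7 of 50 oxidative phosphorylation members lie close to. With TMM 14.8% of called peaks were higher, with DESeq2 size factors 27.3% and with total counts 54.0%. The median of all peaks moved from -0.15 to -0.02 and 0.16. The number called was 9485 without replicate 3, 2597 without replicate 2, 2165 with replicate 3 alone and 700 with only the libraries of this contrast.

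In input libraries of the double knockdown, SLC7A11 (ratio 19.4, 6.29 to 96.9), STMN2 peak 2 (3.70 ± 0.24) and DDIT3 (3.51 ± 0.57) led the rises against control. EGR1, an immediate early gene (ratio 19.4, 5.04 to 166), AP1B1 (ratio 10.7, 3.37 to 54.6) and TARDBP (-3.03 ± 0.21) led the falls among named peaks. DPYSL5, a neuronal collapsin response protein gene, fell by 2.87 ± 0.22. This contrast compares no shallow library, but its dispersions come from the fit that holds them. It called 5190 peaks, 2321 higher and 2869 lower, against 6891 with only its own libraries and 7677 with TDP-43 knockdown input replicate 3 alone. Leaving out 1 library left 3061 to 3450. Cryptic splicing transcripts (13 of 31 lower and 1 higher, 0.00214) and axonal cytoskeleton (10 of 27 lower and 1 higher, 0.00237) were called, each at adjusted p = 0.177 with an estimated correlation. So were ALS and FTD genes (9 of 26 lower and 2 higher, 0.0296) and synaptic vesicle transcripts (9 of 27 lower and 4 higher, 0.0317), with the same estimated value. Integrated stress response targets (8 of 18 higher, 0.0317; adjusted p = 0.223 with an estimated correlation) and ZNF-named zinc fingers (112 of 386 higher and 13 lower, 0.00214; adjusted p = 0.285 with an estimated correlation) were called as well. The remaining calls were ribosomal proteins (26 of 72 higher and 3 lower, 0.0202; adjusted p = 0.752 with an estimated correlation) and progenitor markers (2 of 4 higher, 0.042; adjusted p = 0.177 with an estimated correlation; adjusted p = 0.0705 without control input replicate 3). Against TDP-43 knockdown input, 5550 peaks were called, 4259 higher and 1291 lower, with SEMA3D (ratio 44.3, 12.1 to 369) and CALM2 (-2.73 ± 0.22) among them. There 76.7% of called peaks were higher with TMM, 65.6% with DESeq2 size factors and 40.7% with total counts (medians 0.19, 0.07 and -0.12). The number called was 10376 without TDP-43 knockdown input replicate 3, 3477 without replicate 2, 2806 with replicate 3 alone and 1321 with only the libraries of this contrast. Ribosomal proteins (17 of 72 lower and 2 higher, 2.01e-05; adjusted p = 0.593 with an estimated correlation), oxidative phosphorylation (14 of 50 lower, 1.92e-05; 0.412) and immediate early transcripts (7 of 16 lower, 0.0263; 0.395; EGR1 -2.70 ± 0.53) lost their calls with replicate 3 alone (adjusted p = 0.0791 with the direction turned, 0.393 and 0.0786). The ribosomal call was also lost without replicate 1 (0.0758), and the immediate early call in 2 of 6 cases (up to 0.0559). Long non-coding RNAs (4 of 4 higher, 0.0263; 0.395) did so without replicate 2 (0.0762).

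Enrichment in the knockdown conditions had many features of control neurons. After TDP-43 knockdown 23231 peaks were called (12961 higher, 10270 lower) and in the double knockdown 30830 (15459 and 15371). PLK2 (at least 8.28-fold), PTCHD4 (at least 6.96-fold) and TMEM68 (at least 6.76-fold) led the enriched peaks after TDP-43 knockdown. AGRN (-3.82 ± 0.32) and TUBA1A (-3.32 ± 0.22) led the depleted ones. In the double knockdown ATXN1L (ratio 23.8, 6.54 to 198) and SUB1 (3.87 ± 0.49) were enriched, and CALM2 (-3.83 ± 0.22), IGF2R (-3.62 ± 0.16) and KALRN (-3.42 ± 0.21) depleted. Deadenylases were enriched in both (11 of 17 higher and 2 lower, adjusted p = 0.00135, and adjusted p = 0.141 with an estimated correlation, after TDP-43 knockdown). In the double knockdown 12 were higher and 1 lower (0.000108, and adjusted p = 0.038 with an estimated correlation), with TOB1 at 2.76 ± 0.11. P-body factors were called in the double knockdown (11 of 25 higher and 4 lower, 0.0489, and adjusted p = 0.102 with an estimated correlation; lost without 1 library in 5 of 6 cases, up to 0.0587, and with a replicate block, 0.0521). They were not called after TDP-43 knockdown (adjusted p = 0.0627, where the median was -0.04 and the mean 0.34). Axonal cytoskeleton transcripts were depleted in both (25 and 24 of 27 lower; 3.65e-15 and 4.42e-07; 0.00283 and 0.038 with an estimated correlation). Heat shock transcripts were as well (6 and 6 of 10; 0.000666 and 0.000597; 0.0425 and 0.038 with an estimated correlation). ZNF-named zinc fingers were enriched in both (238 and 238 of 386 higher; 1.31e-12 and 1.92e-08; 0.0385 and 0.0648 with an estimated correlation). The medians of all peaks were 0.23, 0.41 and 0.26 after TDP-43 knockdown with TMM, DESeq2 size factors and total counts (55.8%, 66.3% and 57.3% of called peaks higher). In the double knockdown they were 0.14, 0.39 and 0.50 (50.1%, 65.0% and 70.5%). Without TDP-43 knockdown input replicate 3, 13155 peaks were called after TDP-43 knockdown, 9614 higher and 3541 lower. With that replicate alone the majority turned, with 9008 peaks higher and 10221 lower and a median of all peaks of 0.28.

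Further lists were depleted from DDX6 libraries of both knockdown conditions. Several of the lists below leaned the same way in control neurons without a call. There ALS and FTD genes had 13 of 26 lower and 6 higher (camera adjusted p = 0.0522) and cryptic splicing transcripts 15 of 31 and 6 (0.141). Stress granule proteins had 8 of 20 lower and 4 higher (0.237) and 5' TOP factors 7 of 15 and 2 (0.344). Histones had 6 of 12 and 2 (0.276) and stress response targets 6 of 18 and 2 (0.276). After TDP-43 knockdown and in the double knockdown, ribosomal proteins had 60 and 52 of 72 lower (1.59e-19 and 1.17e-05; adjusted p = 0.101 and 0.605 with an estimated correlation). Oxidative phosphorylation had 38 and 23 of 50 (3.04e-09 and 0.00648; 0.0385 and 0.605) and synaptic vesicle transcripts 17 and 21 of 27 (0.00135 and 0.00648; 0.199 and 0.0648). Stress granule proteins had 14 and 11 of 20 (0.000299 and 0.00986; 0.0225 and 0.21), 5' TOP factors 9 and 9 of 15 (0.000666 and 0.0104; 0.284 and 0.605) and cryptic splicing transcripts 17 and 19 of 31 (0.00958 and 0.00845; 0.341 and 0.224). ALS and FTD genes (17 of 26 lower, 0.00133; 0.0225), histones (9 of 12 lower, 0.000133; 0.0425) and stress response targets (9 of 18 lower, 0.0474; 0.138) were called after TDP-43 knockdown but not in the double knockdown. There ALS and FTD genes lay just past the threshold (12 of 26 lower, adjusted p = 0.0542). Their change of ratio between the 2 knockdown conditions was not called (adjusted p = 0.0781), so no difference was shown for them. The cryptic splicing call after TDP-43 knockdown was lost without input replicate 3 (adjusted p = 0.235), the 5' TOP call with replicate 3 alone (0.0657), and the stress response call in 5 of 6 cases of leaving out a library (up to 0.0612) and with replicate 3 alone (0.193).

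The last comparisons ask whether the DDX6-to-input ratio itself changed. After TDP-43 knockdown MBP (4.57 ± 0.89), LINC01128 (4.49 ± 0.60) and MYH10 (4.39 ± 0.57) rose in ratio. TARDBP (-3.16 ± 0.80), PCDH9 (-3.14 ± 0.51), a protocadherin, and TFRC (-2.74 ± 0.54), the transferrin receptor, fell. Without TDP-43 knockdown input replicate 3 the calls of TARDBP (-2.24, adjusted p = 0.366) and TFRC (-0.40, adjusted p = 0.877) were lost. In the double knockdown against TDP-43 knockdown AP1B1 (4.44 ± 0.69) and CPLX2 (2.71 ± 0.42), a synaptic fusion regulator, rose and RPRD1B (-4.62 ± 0.92) fell. The STMN2 peak 2 rose after TDP-43 knockdown alone by 6.52 ± 0.23 in DDX6 and by 2.78 ± 0.29 in input libraries. Adding DCPS knockdown raised it by 0.37 ± 0.13 in DDX6 and by 0.92 ± 0.20 in input libraries. In the double knockdown against control, NECTIN1 (3.21 ± 0.48), the STMN2 peak 2 (3.19 ± 0.44) and DPYSL5 (2.46 ± 0.27) rose in ratio. TFRC (-3.25 ± 0.45), SNHG14 (-3.20 ± 0.25), TNRC6A (-2.47 ± 0.45) and PABPC1 (-2.46 ± 0.26), the poly(A)-binding protein, fell. As gene sums, P-body factors had 3 of 25 higher and 7 lower there without a call as a list (adjusted p = 0.191), with TNRC6B at -1.63 ± 0.20 and AGO2 at -0.86 ± 0.12. The peaks called were 2402 (1721 higher, 681 lower), 3392 (986 and 2406) and 3452 (1441 and 2011) in the 3 comparisons. Without TDP-43 knockdown input replicate 3 the first 2 numbers were 7315 and 9529. The second fell to 1937 without replicate 2 of that group and to 2082 without double knockdown input replicate 1. The third was 2044 to 2239 without any 1 of its 6 input libraries, 6163 with TDP-43 knockdown input replicate 3 alone and 6500 with only the libraries of its contrast.

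Ribosomal proteins fell in ratio after TDP-43 knockdown (44 of 72 lower and 0 higher, 51 and 1 adjusted over the list alone; 6.29e-20, and adjusted p = 0.28 with an estimated correlation), and histones too (9 of 12 lower; 6.04e-05, and adjusted p = 0.155 with an estimated correlation). Also lower as groups were 5' TOP factors (7 of 15, 0.000137; 0.529), stress granule proteins (10 of 20, 0.00191; 0.155) and axonal cytoskeleton (9 of 27, 0.00749; 0.28), the second value again with an estimated correlation. So were cryptic splicing transcripts (13 of 31, 0.0141; 0.529) and ALS and FTD genes (6 of 26, 0.0454; 0.28). The cryptic splicing call was lost without TDP-43 knockdown input replicate 3 (0.773), and the ALS call without 1 library in 5 of 12 cases (up to 0.109). Oxidative phosphorylation was called as well (0.00799; 0.568), but only 5 of 50 members were lower, against 918 of all 7968 genes, and 0 adjusted over the list alone. That call was lost without replicate 1 (0.197) or replicate 2 (0.145) of the same input group. In the double against the TDP-43 knockdown ribosomal proteins rose (31 of 72 higher and 1 lower; 1.7e-10, and adjusted p = 0.474 with an estimated correlation), as did oxidative phosphorylation (13 of 50 higher; 5.41e-05; 0.474). Also higher were histones (9 of 12 higher; 9.13e-05), axonal cytoskeleton (15 of 27 higher and 1 lower; 9.13e-05) and stress response targets (7 of 18 higher; 0.0035), each at adjusted p = 0.0941 with an estimated correlation. Long non-coding RNAs fell (4 of 4 lower; 0.0035; adjusted p = 0.0941 with an estimated correlation). ZNF-named zinc fingers fell in the double knockdown against control (126 of 386 lower and 8 higher; 2.42e-06, and adjusted p = 0.302 with an estimated correlation) and against TDP-43 knockdown (76 lower and 18 higher; 0.00789; adjusted p = 0.324 with an estimated correlation). Against control the long non-coding RNAs fell as well (3 of 4 lower; 0.0196; adjusted p = 0.302 with an estimated correlation). With TDP-43 knockdown input replicate 3 alone, the ribosomal and histone calls of the double against the TDP-43 knockdown were lost (0.35 and 0.0926), as were the zinc finger and oxidative phosphorylation calls there (0.11 and 0.496). After TDP-43 knockdown the histone, stress granule, 5' TOP and ALS calls were lost in that fit (0.0958, 0.0958, 0.283 and 0.257), and the oxidative phosphorylation result turned direction (0.515). The direction of most called peaks turns with the scaling: 71.7%, 61.5% and 36.8% were higher after TDP-43 knockdown with TMM, DESeq2 size factors and total counts (medians 0.10, 0.03 and -0.15). The shares were 29.1%, 37.0% and 71.0% in the double against the TDP-43 knockdown (medians -0.17, -0.09 and 0.17), and 41.7%, 40.0% and 52.3% in the double knockdown against control.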

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

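The depth test of the shallow libraries, the mixtures with single groups, the noise correction of the slopes and the use of r beside the covariance were chosen only after the results had been seen; the other tests were written down before they were run.

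DDX6-to-input ratios differed between conditions for 2402 peaks after TDP-43 knockdown, 3392 in the double against the TDP-43 knockdown and 3452 in the double knockdown against control. With the preset correlation 8, 7 and 2 gene lists were called, and with an estimated correlation 0 in each. After TDP-43 knockdown alone the STMN2 peak 2 had already risen more in DDX6 (6.52 ± 0.23) than in input libraries (2.78 ± 0.29). SNHG14, TFRC and TNRC6A fell in ratio and NECTIN1 and the STMN2 peak 2 rose in the last comparison, the double knockdown against control. It compares no shallow library but takes its dispersions from the fit that holds them, and called 6163 peaks with TDP-43 knockdown input replicate 3 alone but 2044 to 2239 without any 1 of its 6 input libraries. Refitting only the libraries of a contrast with the group labels redrawn, 1 of 80 splits, the real one, called as many peaks in each: 1735 against a highest other of 1721, 2253 against 530 and 6500 against 2647. For the other 9 comparisons only 10 splits exist, too few for a share under 0.05, and 1 of 10, the real one, called as many in each. The real splits called 32489, 17821 and 31729 peaks for DDX6 against input in control, TDP-43 knockdown and double knockdown, 28717, 22846 and 26293 between DDX6 libraries (TDP-43 knockdown against control, double against TDP-43 knockdown, double against control) and 700, 1321 and 6891 between input libraries in the same order, while edgeR called 0 in every other split. A split that mixes the groups takes their real differences in as spread, which lowers the number called. Low numbers in other splits are thus partly built in and do not by themselves show a difference beyond chance.

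Peaks such as the one in CCAR1 rose after TDP-43 knockdown and fell when DCPS knockdown was added, which noise in the libraries shared by both comparisons could produce. The covariance of -0.155 lay beyond the lowest value simulated for unchanged groups, -0.0257, which speaks against noise alone, while r, -0.503 within -0.511 to -0.499 simulated, does not tell a reversal from any other difference of the shared group. A weaker TDP-43 knockdown in the double knockdown, where TARDBP stood 1.58-fold higher in DDX6 libraries, might undo changes as well. In input libraries TARDBP did not pass the test between the double and the TDP-43 knockdown (-0.02 ± 0.27, adjusted p = 0.973), on 109 and 51 counts. A weaker knockdown predicts that cryptic splicing transcripts are undone at least as much as other genes. Their slope was -0.212 ± 0.08 (31 genes) against -0.451 ± 0.02 for 7936 others, a difference of 0.24 ± 0.08 in the other direction. This speaks against a weaker knockdown as the whole cause. The slope of the listed genes was itself negative, which a weaker knockdown would also give. A difference of the TDP-43 knockdown group of another origin would steepen the slope of the others, so the test cannot exclude a part. That the TDP-43 knockdown libraries differ technically as a group, or that DCPS loss acts on the same RNAs, stays open, since no group with DCPS shRNA alone is among the samples.

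TDP-43 knockdown input replicates 1 and 2 stood apart from replicate 3, and ribosomal protein transcripts moved with them. Low depth alone would leave chi-square per degree of freedom in the range of other replicate pairs, but the smaller of the values was 2.83 against a highest of 1.40 in the other groups, and replicates 1 and 2 also differed from each other by more than that (1.54). This holds where each count is a separate molecule. How duplicates were handled is not known, so the test cannot exclude duplicates in these shallow replicates. Reads from the other libraries could also set them apart, but a fitted mixture took 4% and 0% from the pool and left 2.76 and 3.16, and with each other group as the source 2.75 to 3.16, which speaks against them as the whole cause. TARDBP goes with them in part, with 13 counts in replicate 1 against 4.09 from the mixture and 9 against 6.6 in replicate 2. No biological explanation was tested.

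In 14 genes of the 5735 with at least 3 peaks, a peak rose at least 2-fold after TDP-43 knockdown while the median of the gene's other peaks did not rise. STMN2 came first (6.52, from 1.45 to 136 CPM in DDX6 libraries). Next were ABLIM3 (1.46 ± 0.54, from 0.417 to 1.19 CPM) and MICAL3 (1.37 ± 0.27, from 2.32 to 6.18 CPM). After STMN2 the MICAL3 peak was the highest of the 14 after TDP-43 knockdown, so the other peaks rest on few counts. Cryptic exons repressed by TDP-43 may explain them: of 24 listed genes 1, STMN2, had such a peak, an odds ratio of 19 (0.43 to 137, Fisher's exact p = 0.0571; p = 0.0834 against genes matched by draws), which leaves the matter undecided. By the same rule 43 peaks rose in the double knockdown, some of them in the same gene such as STMN2, and 12 (27.9%) were called higher after TDP-43 knockdown alone, between the limits set for and against a shared cause, and also undecided.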

How the results depend on the processing

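The fit with TDP-43 knockdown input replicate 3 alone, the newer quasi-likelihood method and the features by peak length and 3' distance were chosen after the data were seen.

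Of 240 named peaks, 238 kept their call with DESeq2 size factors, 229 with the DESeq2 Wald test, 236 with a replicate block and 220 with replicate 3 alone, and 1685 of 1800 results held on leaving out 1 library; none turned direction. Of 94 list calls, 93 held with DESeq2 size factors, 91 with a replicate block, 73 with replicate 3 alone and 21 with an estimated correlation, and 585 of 666 results held on leaving out 1 library. With replicate 3 alone 2 turned: oxidative phosphorylation in the change of ratio after TDP-43 knockdown (adjusted p = 0.515) and ribosomal proteins in input of the double against the TDP-43 knockdown (0.0791).

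Counts of called genes are not counts of peaks. Summed per gene, DDX6 against input gave 4875 genes in control, 4600 after TDP-43 knockdown and 4932 in the double knockdown. Between DDX6 libraries 4378, 3676 and 3680 genes were called (TDP-43 knockdown against control, double against TDP-43 knockdown, double against control), between input libraries 2096, 2491 and 2805, and for the change of ratio 1782, 2116 and 1997.

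With replicate 3 alone, 2117 and 6163 peaks were called for the change of ratio in the double knockdown against TDP-43 knockdown and against control, and 2165 and 2806 between input libraries of TDP-43 knockdown and control and of double and TDP-43 knockdown. With only the libraries of a contrast these 4 numbers were 2253, 6500, 700 and 1321.

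Leaving out 1 library gave 26335 to 27006 peaks for enrichment in control, 13155 (without TDP-43 knockdown input replicate 3) to 21489 after TDP-43 knockdown and 24714 to 26209 in the double knockdown. Between DDX6 libraries the ranges were 16228 to 16914, 11547 to 12239 and 12351 to 13085, and between input libraries 2597 to 9485, 3477 to 10376 and 3061 to 3450. For the change of ratio they were 1677 to 7315, 1937 to 9529 and 2044 to 3624; the values 9485, 10376, 7315 and 9529 came from leaving out TDP-43 knockdown input replicate 3. The correlation of changes ranged from -0.558 to -0.512 in DDX6 libraries (-0.466 with no filter) and from -0.904 to -0.643 in input libraries, and list calls from 80 to 119. The excess of enriched over depleted peaks near the 3' end was 24.4 points of percent, 27.1 at 2-fold and 21.7 with total counts.

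Features by exon, untranslated region or GC content and peaks lying mostly in exons were planned and not run, because the annotation used here has no exons or sequence.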

Other observations

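The genes of this part were picked after their values were seen, from lists fixed beforehand. Adding DCPS knockdown to TDP-43 knockdown moved several neuronal signal genes in DDX6 libraries without a call for their list. Among postsynaptic transcripts, 12 of 26 rose and 5 fell (adjusted p = 0.306): the glutamate receptor genes GRIN2A (-2.10 ± 0.08), GRIN2B (-2.02 ± 0.12) and GRIA3 (-1.40 ± 0.08) fell, and the scaffold gene DLG2 rose (1.47 ± 0.08). Immediate early transcripts had 3 of 16 higher and 6 lower (0.306), with EGR1 (-1.18 ± 0.12) lower and IER2 higher (1.15 ± 0.15). Peripheral-like neuron markers had 2 of 6 higher and 0 lower (0.185), the neuropeptide precursor TAC1 (2.12 ± 0.17) and the acetylcholine synthesis gene CHAT (0.84 ± 0.09).

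Other lists without a call in this comparison were exosome and cap scavenging factors (4 of 12 higher and 1 lower, adjusted p = 0.546), to which DCPS itself belongs, p53 targets (1 and 4 of 14, 0.674), stress granule proteins (5 and 3 of 20, 0.546) and ion channels (7 and 3 of 19, 0.546). Transcripts with cryptic splicing were partly higher, such as ELAVL3 (0.88 ± 0.13) and UNC13A (0.71 ± 0.12), though both stayed below control.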
